A study of Homo sapiens with 7 samples.

How the data were processed

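RNA was measured on 7 single-colour Affymetrix arrays, 1 per culture of human pulmonary artery smooth muscle cells. The cells came from patients with idiopathic pulmonary arterial hypertension (IPAH) or from patients without pulmonary hypertension (normotensive), and were kept for 24 h with vehicle, called untreated here, or with 200 nM BMP-2. The groups, taken from the labels, were normotensive untreated (1 array), normotensive with BMP-2 (2), IPAH untreated (2) and IPAH with BMP-2 (2). The labels number the cell isolates within each origin. They do not say that the numbered isolates came from different donors or were cultured separately, so the p-values measure only the spread between these samples, which may be technical.

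The deposited values are linear signal intensities, 12625 probe sets per array, with no centring of genes. The mean signal after trimming 2% of the values at each end was 150.1 on every array and differed by 0.0145% between arrays, so the deposited intensities were already scaled to a common trimmed mean. Per the labels, targets were made from total RNA by standard Affymetrix procedures. The summary algorithm, the background step and the detection calls are not given in the sources used here. Without detection calls no bound on dim genes was set, and the number of arrays limits the precision. A fold change of a gene with a signal near the offset depends on that offset and can understate the change.

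Probe sets were named through the platform annotation and the RefSeq gene table of GRCh38.p14. Of the probe sets, 67 were controls, 10927 had 1 gene symbol, 533 had several and 1070 had none. Of those with 1 symbol, 10918 matched the gene table by gene number, and no symbol had to be updated. XIST and Y-linked genes (28 probe sets) were left out before any step. The 8210 genes were each represented by the probe set with the highest mean log2 signal, and 1928 of them had more than 1 probe set. Probe sets with several symbols or none were tested only in an alternative, and no gene was named from them.

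An offset of 13, the median of all values divided by 4, was added before log2. No further scaling was needed because the trimmed means differed by less than the preset limit. Genes in the upper 60% by mean log2 signal were tested, 4926 in all, which set the floor at a log2 of 5.79 or a signal of 42.3. All fold changes are on the log2(signal + 13) scale.

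Linear models were fitted with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a variance trend), with 1 mean for each of the 4 groups and all 7 arrays sharing 1 estimate of the spread. That fit had 3 residual degrees of freedom and a prior worth 3.88. The normotensive untreated group had 1 array, so its spread was assumed to equal that of the other groups. From it came the effect of BMP-2 in IPAH cells, the effect in normotensive cells, the difference between origins without BMP-2 and with it, and the difference between the BMP-2 effects (interaction). The BMP-2 effect over both origins came from an additive model of origin and treatment, with 4 residual degrees of freedom. An adjusted p under 0.05 (Benjamini-Hochberg over the 4926 genes) was the threshold, and adjusted p always means limma's.

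A total of 29 gene lists covered BMP and TGF-beta signalling, contraction, matrix, cell cycle, apoptosis, ion channels, vasoactive and growth factors, inflammation, metabolism, stress, and markers of other cell types. Each list with at least 5 tested members was tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison. None of the 20 list calls held when camera estimated the correlation between genes. Counts within a list are given over all genes and adjusted over the list alone.

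The genes named were, in each comparison, the 10 highest and 10 lowest fold changes past the threshold, or all of them if fewer. Where fewer than 10 passed, the 10 genes with the smallest p were named too. Up to 4 members of each list described, and BMPR2, ID1, ID2, ID3, SMAD6, SMAD7, KCNA5 and BCL2, were also named. Genes named outside this rule are said to be so. Immunoglobulin, HLA and commonly deleted genes were not named. The grouping, the tests, the lists, this rule and all alternatives but 1 were fixed before the data were examined.

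The alternatives were offsets of 1 and of the median, no filter, a filter to the upper 40%, quantile normalization, median centring, all probe sets, no variance trend, the comparison's own arrays, each array left out in turn, an adjusted p under 0.10, and the isolate as a block. Median centring moved the median log2 difference of all tested genes between origins from 0.09 to -0.14 without BMP-2 and from 0.09 to -0.06 with it, and that of the BMP-2 effect in IPAH cells from -0.03 to 0.13. Under it the 49 genes that differed between untreated cells (23 higher, 26 lower in IPAH) became 57 (20 higher, 37 lower).

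The labels give untreated and treated arrays the same isolate numbers, and arrays with the same number and origin were taken as 1 isolate, so the numbers pair the samples. In IPAH cells the deviations of paired arrays from their group means correlated at r = 0.452 across genes, which are not independent replicates, and the consensus correlation of arrays of 1 isolate was 0.402. The isolate was fitted as a random effect and, for the BMP-2 comparisons, as a fixed term. Both IPAH isolates had both treatments, as did 1 normotensive isolate. With the fixed term and 1 effect per origin, the fit kept 1 residual degree of freedom in all, which came from the IPAH pairs, and an infinite prior. The normotensive arrays left 0, so their effect in that fit was the difference of 1 pair.

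The procedure was tested on simulated data for the 4926 genes, with independent normal noise and no isolate effects. Of simulated log2 changes of 2, it recovered 77.6% for BMP-2 in IPAH cells, 47.8% for BMP-2 in normotensive cells, 95.5% over both origins, 55.2% between untreated origins, 83.6% between treated origins and 13.4% for the interaction. Of changes of 1, it recovered 17.9%, 1.49%, 32.8%, 7.46%, 16.4% and 1.49% in the same order. False calls were 11 of 140, 6 of 94, 4 of 156, 10 of 112, 12 of 143 and 6 of 70 calls in that order, above the nominal share in each comparison but that over both origins. Each run changed 66 or 67 genes at each size. Where far fewer genes change, as with the few that passed for BMP-2, the adjusted threshold is stricter. These shares can therefore overstate the recovery in the real data. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.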

Results

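The expression of 8210 genes was measured in cultured pulmonary artery smooth muscle cells, the contractile cells of the vessel wall that thickens in pulmonary hypertension. BMP-2 is a bone morphogenetic protein, a ligand whose receptors signal through SMAD transcription factors. Mutations of the type II receptor gene BMPR2 are a known cause of heritable disease. The 4 groups held 1 to 2 arrays each, 7 in all, and the median signal per array lay between 44.3 and 62.4. The first principal component took 46.7% of the variance and separated the origins. Its scores ran from 8.98 to 36.2 on the 4 IPAH arrays and from -31.6 to -28.9 on the 3 normotensive arrays. The second took 19.4% and separated the 2 IPAH isolates, at 16.7 or above and at -22.8 or below. IPAH BMP-2 replicate 2 correlated at r = 0.870 with normotensive BMP-2 replicate 2 and at 0.873 with IPAH BMP-2 replicate 1. IPAH BMP-2 replicate 1 correlated with the normotensive arrays at 0.796 to 0.812. Differences between the IPAH isolates were therefore not small beside those between origins. The median standard deviation between the 2 arrays of a group was 0.18 in normotensive cells with BMP-2, 0.31 in untreated IPAH cells and 0.29 in IPAH cells with BMP-2, on the log2 scale.

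The first comparison asked which genes BMP-2 changed in IPAH cells (2 arrays against 2). ID1, an inhibitor of helix-loop-helix transcription factors and a direct SMAD target, rose by 5.70 ± 0.25 (log2, SE; adjusted p = 5.2e-04). Its mean signal was 164 ± 19.3 (SD, n = 2) without and 9268 ± 2267 (n = 2) with BMP-2. All 3 probe sets of ID1 rose, by 1.33 to 5.70, and the one used gave the largest change. ID3, of the same family, rose by 3.20 ± 0.28 (adjusted p = 0.0224), from a signal of 279 to one of 2743. No gene fell. Other genes with small p did not pass. They included the actin ACTC1 at 3.15 ± 0.43 (adjusted p = 0.162), the tropomyosin TPM1 at 2.04 ± 0.26 (adjusted p = 0.152) and CBFB, a partner of RUNX factors, at 1.73 ± 0.20 (adjusted p = 0.113). RBM42 at 2.11 ± 0.31, NFATC4 at -2.24 ± 0.36, GJB1 at -1.60 ± 0.29 and LRIG1 at -1.54 ± 0.29 did not pass either, and 1 of the 4 probe sets of NFATC4 had the opposite sign. The inhibitory SMAD genes SMAD6, at 3.42 ± 0.64 (adjusted p = 0.597), and SMAD7, at 2.07 ± 0.50 (adjusted p = 0.838), did not pass. Both were higher with BMP-2 in both pairs of arrays, SMAD6 from a signal of 78.7 to 622.1 and from 9.5 to 360, and their untreated IPAH arrays differed widely. Over the alternatives SMAD6 ranged from 2.41 to 4.44 and SMAD7 from 1.35 to 2.80. The 2 probe sets of SMAD6 rose by 2.24 and 3.42. With the isolate as a fixed term, in a fit with 1 residual degree of freedom and an infinite prior, SMAD6 (adjusted p = 8.7e-22) and SMAD7 (adjusted p = 5.7e-08) passed, as did each other gene named here as short of the threshold. Such a prior replaces each gene's own spread by a common trend, so these p-values do not measure how well a gene repeats.

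In the list of BMP-SMAD targets, 2 of 13 tested members rose and 5 rose adjusted over the list alone: ID1, ID3, SMAD6, SMAD7 and HES1. The median of the list was 0.65 (camera adjusted p = 3.3e-05), and the adjusted p was 0.444 with an estimated correlation. The median depended on which members were tested, being -0.17 without the filter and 1.34 in the upper 40% of genes, with camera calls upward in both. It was 0.30 and 1.19 without untreated IPAH replicate 1 and 2, and 1.15 without IPAH BMP-2 replicate 1. Ribosomal protein genes had a median of 0.23 over 44 members, none of which passed, also adjusted over the list alone (camera adjusted p = 4.7e-06, adjusted p = 0.947 with an estimated correlation). Under quantile normalization that median was 0.08 and its call ended, as it did without IPAH BMP-2 replicate 1 (0.11) or untreated replicate 2 (0.09). The log2 3'/5' ratio of GAPDH, a sign of RNA quality, was lower with BMP-2 in both pairs of IPAH arrays (-0.34 and -0.82), as was that of ACTB (-0.70 and -0.94). With its call kept the ribosomal median was 0.36 without untreated replicate 1, 0.37 without IPAH BMP-2 replicate 2 and 0.39 under median centring.

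Only ID1 and ID3 passed among the 4926 genes with BMP-2 in IPAH cells, and 261 had an unadjusted p under 0.05 where 246.3 were due by chance. With the isolate as a random block the count was 5, all higher, which added CBFB, TPM1 and ACTC1, and with the isolate as a fixed term it was 112 (70 higher, 42 lower). The call of ID3 ended when the spread was taken from these 4 arrays alone (adjusted p = 0.168, over the alternatives 5.9e-51 to 0.202), without the variance trend, and without any 1 of 5 arrays: either normotensive BMP-2 array, either untreated IPAH array, or IPAH BMP-2 replicate 2.

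The second comparison asked the same of normotensive cells (2 treated arrays against 1 untreated). ID1 rose by 5.69 ± 0.31 (adjusted p = 0.00206), from a signal of 88.7 on the untreated array to 5249 ± 536 (SD, n = 2). Its 3 probe sets rose by 0.82 to 5.69. ACTC1 had a log2 fold change of 4.54 ± 0.52 (adjusted p = 0.144) and ID3 one of 2.72 ± 0.34 (adjusted p = 0.157), and neither passed. The others with the smallest p did not pass: TMEM158 at -1.92 ± 0.27, SPRR2D at 2.10 ± 0.31, XYLT1 at 2.91 ± 0.52, CSRP2 at 1.52 ± 0.30, BCAT2 at 2.11 ± 0.46, CEP164 at 1.61 ± 0.36 and ZBTB1 at 2.52 ± 0.57. SMAD6 was at 2.73 ± 0.78 and SMAD7 at 2.19 ± 0.61, likewise short of the threshold.

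Of the 13 BMP-SMAD targets 1 rose in normotensive cells, and 6 rose adjusted over the list alone: ID1, ID3, SMAD6, SMAD7, HES1 and BAMBI, a decoy receptor. The list's median was 1.66 (camera adjusted p = 3.5e-07, adjusted p = 0.264 with an estimated correlation), and it was 0.49 without the filter, 1.0 in the upper 40% of genes and 0.81 with all probe sets. None of 23 smooth muscle contractile genes passed, although 2, CSRP2 and TPM1 (1.37 ± 0.32), rose adjusted over the list alone. Their median was 0.36 (camera adjusted p = 0.00365, adjusted p = 0.827 with an estimated correlation), or 0.23 without the filter. Ribosomal protein genes had a median of -0.15 with no member past the threshold, also over the list alone (camera adjusted p = 0.0134, adjusted p = 0.827 with an estimated correlation). That last call ended under quantile normalization, median centring (-0.06), no filter and no variance trend, and without normotensive BMP-2 replicate 1 (-0.13).

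ID1 was the 1 gene past the threshold, and 170 genes had an unadjusted p under 0.05. With the isolate as a random block ID1, ID3 and ACTC1 passed (3 genes), and with the isolate as a fixed term 24 did (17 higher, 7 lower). That last fit sets 1 treated normotensive array against 1 untreated one and takes its spread from the IPAH pairs, so its calls say little about normotensive cells. Without either BMP-2 array no gene passed and the adjusted p of ID1 reached 0.0741 (range over the alternatives 2.5e-74 to 0.0741).

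**Figure D1:**
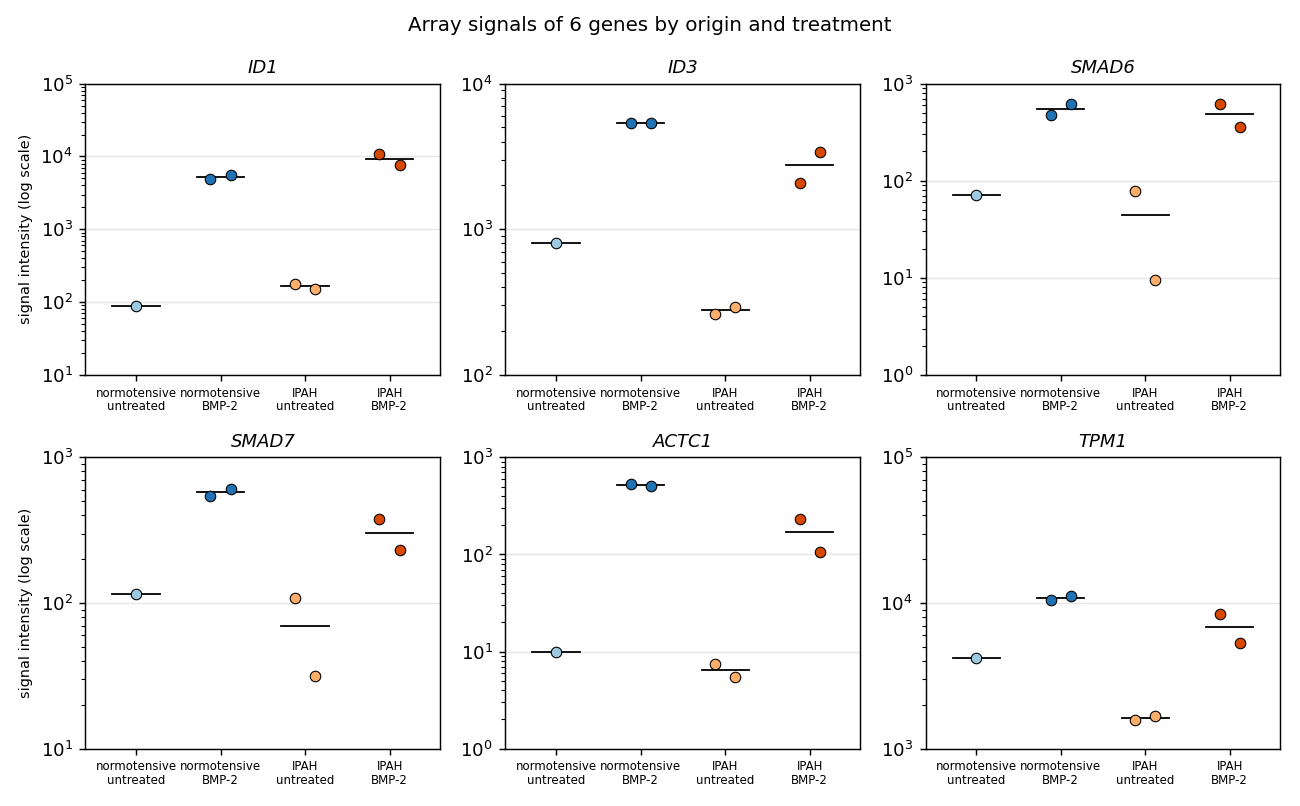
Signal intensity on a log axis for 6 genes in the 4 groups, with a point for each of the 7 arrays and a line at each group mean. ID1 lay between 88.7 and 177.5 on the 3 untreated arrays and between 4869 and 10871 on the 4 arrays with BMP-2, while the 2 untreated IPAH points of SMAD6 and of SMAD7 lay far apart.

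Over both origins (4 arrays with BMP-2 against 3 without, additive model), 4 genes rose with BMP-2 and none fell. ID1 rose by 5.69 ± 0.18 (adjusted p = 2.8e-06), ID3 by 3.01 ± 0.21 (adjusted p = 9.9e-04), ACTC1, the cardiac alpha-actin, by 3.71 ± 0.39 (adjusted p = 0.0149), and TPM1 by 1.77 ± 0.22 (adjusted p = 0.0453). Every array with BMP-2 had a higher signal of these 4 genes than every array without. ACTC1 lay between 5.5 and 10 without BMP-2 and between 106.5 and 535.1 with it, and TPM1 between 1567 and 4190 and between 5356 and 11192. All 3 probe sets of TPM1 had the same sign, as did the 3 of ID1, which ranged from 1.12 to 5.69.

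Other genes with small p did not pass over both origins: SMAD6 at 3.15 ± 0.47 (adjusted p = 0.116), SMAD7 at 2.12 ± 0.35 (adjusted p = 0.217), the NOTCH and BMP target HES1 at 1.90 ± 0.35, CLDN14 at 1.57 ± 0.27, GSE1 at 1.14 ± 0.21 and UNC5B at 0.87 ± 0.17. KCNA5, a voltage-gated potassium channel of these cells, had a log2 fold change of 0.58 ± 0.28 (adjusted p = 0.856, 0.32 to 0.75 over the alternatives), and the survival gene BCL2 one of 0.48 ± 0.49 (adjusted p = 0.913), with probe sets of both signs. BMPR2 and ID2 lay below the signal filter and were not tested. Their signals ranged from 1.7 to 53.8 and from 13.1 to 56.7. Each was read from 1 probe set, since probe sets with several symbols were not used for any gene. A low signal there therefore does not show that the transcript was scarce.

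Of the 13 BMP-SMAD targets 2 rose over both origins and 6 rose adjusted over the list alone, ID1, ID3, SMAD6, SMAD7, HES1 and BAMBI, with a median of 1.06 (camera adjusted p = 1.1e-07, adjusted p = 0.0968 with an estimated correlation). That median was 0.07 without the filter, 0.30 with an offset of 1, 0.29 with all probe sets, 0.65 without the normotensive untreated array and 0.54 without IPAH BMP-2 replicate 1, with the camera call kept in each. Among 23 contractile genes TPM1 rose, and TPM1 and CSRP2 (0.95 ± 0.24, 0.58 to 1.09 over the alternatives) rose adjusted over the list alone, with a list median of 0.12 (camera adjusted p = 0.00915, adjusted p = 0.699 with an estimated correlation). ACTA2, the smooth muscle alpha-actin of that list, stood at 1.29 ± 0.42 (adjusted p = 0.774), or at 0.75 to 1.74 over the alternatives. None of 30 inflammatory genes passed, over all genes or over the list alone. Their median was -0.36 (camera adjusted p = 0.0160, adjusted p = 0.699 with an estimated correlation), with NFKB2 at -0.96 ± 0.30 (-1.17 to -0.65 over the alternatives) and ICAM1 at -1.20 ± 0.40 (-1.58 to -0.71). The 5 probe sets of NFKB2 ranged from -1.60 to 0.18, and 4 of them were lower with BMP-2. None of 28 interferon response genes passed by either count. Their median was -0.21 (camera adjusted p = 0.0245, adjusted p = 0.699 with an estimated correlation), with PSMB9 at -0.85 ± 0.29. The calls of the contractile, inflammatory and interferon lists ended under quantile normalization, and that of the inflammatory list also without the filter. All 3 ended without the normotensive untreated array (0.14, -0.37 and -0.23) or IPAH BMP-2 replicate 1 (0.03, -0.25 and -0.09). The inflammatory call also ended without untreated IPAH replicate 2 (-0.22) and the interferon call without untreated IPAH replicate 1 (-0.23). With their calls kept, the contractile median was 0.24 without untreated IPAH replicate 1, 0.22 without IPAH BMP-2 replicate 2, 0.25 under median centring and 0.19 with all probe sets. The interferon median was -0.33 without IPAH BMP-2 replicate 2 and -0.08 under median centring, and the inflammatory one -0.23 under median centring.

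Unadjusted, 274 genes had a p under 0.05 over both origins. With the isolate as a fixed term 9 passed: the 4 above and SMAD6 (3.14 ± 0.30), SMAD7 (2.09 ± 0.23), CLDN14 (1.63 ± 0.25) and MARCKS (1.01 ± 0.16), all higher, and PPL, lower (-2.46 ± 0.32), MARCKS and PPL being named after their values were seen. Only ID1 and ID3 passed without the normotensive untreated array, either normotensive BMP-2 array or IPAH BMP-2 replicate 1, and TPM1 lost its call under 11 of 19 alternatives (adjusted p from 0.00271 to 0.258). With an offset equal to the median signal ACTC1 was at 2.41, past the threshold.

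**Figure D2:**
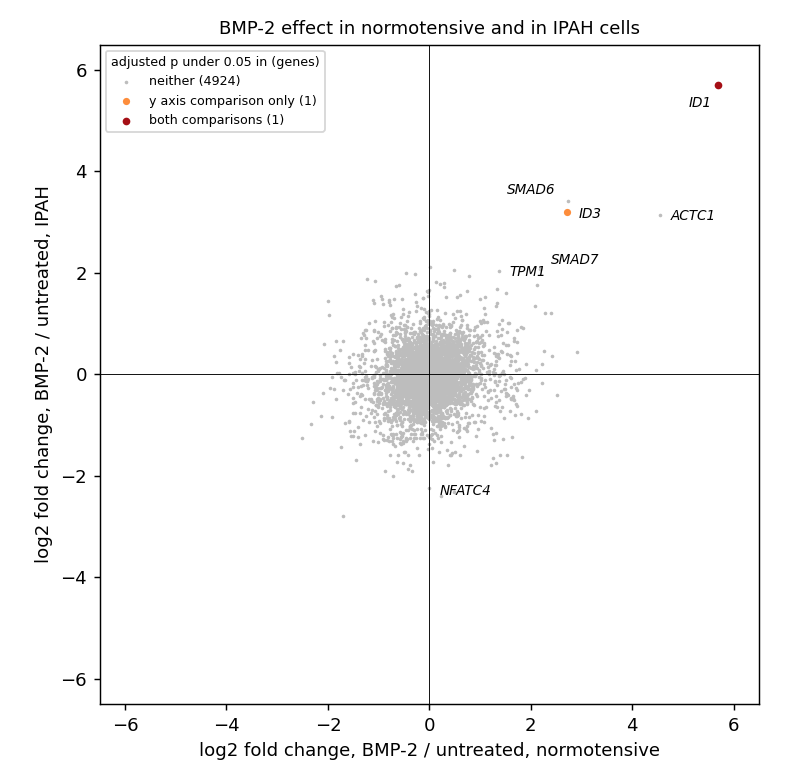
Log2 fold change with BMP-2 in IPAH cells (vertical) against that in normotensive cells (horizontal) for 4926 genes, coloured by the comparisons in which the gene passed the threshold. ID1, at 5.69 and 5.70, passed in both and ID3 in IPAH cells, and Pearson's r over all genes was 0.163.

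The BMP-2 effects of the 2 origins were then set against each other. No gene differed between IPAH and normotensive cells in its response to BMP-2 by limma's interaction test, and 143 genes had an unadjusted p under 0.05 where 246.3 were due by chance. The difference for ID1 was 0.01 (95% interval -0.94 to 0.95), for ID3 0.48 (-0.56 to 1.51), for SMAD6 0.69 (-1.71 to 3.09), for SMAD7 -0.11 (-1.97 to 1.75), for ACTC1 -1.40 (upper limit 0.20) and for TPM1 0.67 (-0.31 to 1.66), so differences of 1 log2 unit were not excluded for ID3, SMAD6, SMAD7, ACTC1 or TPM1. The 10 genes with the smallest p did not pass: ASIC2, SPRR2D, CSNK1G2, BCAT2, RCAN2, TNFRSF10C and CEP164 with values from -3.44 to -1.89, and AURKB, OPLAH and CBFB with values from 1.44 to 3.44. Ribosomal protein genes were the 1 list with a call, with a median difference of 0.38 and no member past the threshold by either count (camera adjusted p = 1.4e-08, adjusted p = 0.993 with an estimated correlation). Beside this, the log2 3'/5' ratio of GAPDH differed between treated and untreated arrays by -0.34 and -0.82 in the 2 IPAH pairs and by 0.11 in the normotensive pair, and that of ACTB by -0.70, -0.94 and 0.26.

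With the isolate as a fixed term, 13 genes passed the interaction test (11 higher, 2 lower in IPAH), but in that fit the normotensive effect is that of a single pair of arrays and the spread comes from the IPAH pairs alone. Over all 4926 genes the 2 sets of BMP-2 fold changes, which share no array, had a Pearson's r of 0.163 and a Spearman's rho of 0.132, and 55.3% of genes had the same sign. Genes are not independent replicates, so these describe the arrays. The r was 0.0897 without the filter, 0.262 in the upper 40% of genes, 0.0563 without IPAH untreated replicate 1 and 0.105 without IPAH BMP-2 replicate 2.

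Without BMP-2, IPAH cells (2 arrays) and normotensive cells (1 array) differed in 49 genes, 23 higher and 26 lower in IPAH. Inflammatory genes were among the lower ones. The neutrophil chemokine CXCL6 had a log2 difference of -8.06 ± 1.08 (adjusted p = 0.0266), the prostaglandin synthase PTGS2 one of -5.92 ± 0.69 (adjusted p = 0.0182), the granulocyte growth factor CSF3 one of -5.77 ± 0.38 (adjusted p = 0.00189) and the cytokine IL1B one of -5.58 ± 0.47 (adjusted p = 0.00431). The signal of CXCL6 was 10792 on the normotensive array and averaged 41.8 ± 52.3 (SD, n = 2) in IPAH. Also lower were STC1, a secreted glycoprotein hormone (-6.18 ± 0.43), the NF-kB inhibitor TNFAIP3 (-4.50 ± 0.30), LRRC15 (-4.13 ± 0.38), the interferon-induced BST2 (-3.89 ± 0.60), IER3 (-3.83 ± 0.25) and NAMPT (-3.60 ± 0.32).

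Higher in untreated IPAH cells were SELENOP, a selenium transport protein (6.23 ± 0.44, adjusted p = 0.00189), the alcohol dehydrogenase genes ADH1A (6.11 ± 0.35) and ADH1B (4.21 ± 0.44), and the growth factor PTN (4.32 ± 0.36). So were NOTCH3, a receptor of vascular smooth muscle (4.23 ± 0.38, adjusted p = 0.00557), and the transcription factors TBX2 (4.42 ± 0.63) and OSR2 (3.97 ± 0.51). MEST (4.10 ± 0.52), RCAN2 (3.62 ± 0.38) and SECTM1 (3.59 ± 0.45) were higher too. The signal of SELENOP was 3.0 on the normotensive array and 1193 on average in IPAH. ADH1A and ADH1B, like the CXCL chemokines, belong to families of similar sequence whose probe sets can cross-hybridise, so the gene behind each signal is uncertain. The second probe set of ADH1A was at 0.43.

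Of the lists, the inflammatory one stood lowest, with 7 of 30 members lower and none higher over all genes, and 20 lower and 1 higher adjusted over the list alone. Its median was -1.80 (camera adjusted p = 3.9e-18, adjusted p = 0.199 with an estimated correlation), and -3.02 in the upper 40% of genes. Of 32 hypoxia and glycolysis genes 4 were lower, the glycolytic enzymes LDHA (-2.41 ± 0.27), ENO2 (-2.28 ± 0.33), TPI1 (-1.64 ± 0.26) and ENO1 (-1.60 ± 0.26), and 12 were lower adjusted over the list alone. TPI1 lost its call under 9 and ENO1 under 10 of 16 alternatives (adjusted p up to 0.197 for both), and LDHA under 3 and ENO2 under 5. The list's median was -0.73 (camera adjusted p = 4.7e-09, adjusted p = 0.160 with an estimated correlation). Of 41 collagen and matrix genes THBS2, an antiangiogenic matrix protein, was lower (-2.20 ± 0.30), and 3 were lower adjusted over the list alone. Their median was -0.78 (camera adjusted p = 0.00130, adjusted p = 0.553 with an estimated correlation). Of 21 immediate early genes IER3 was lower, and 2 were lower adjusted over the list alone, with a median of -0.28 (camera adjusted p = 0.0212, adjusted p = 0.869 with an estimated correlation). Ribosomal protein genes had a median of -0.21 and no member past the threshold by either count (camera adjusted p = 0.00130, adjusted p = 0.869 with an estimated correlation), and under quantile normalization that median was 0.03. The calls of the matrix and immediate early lists also ended under quantile normalization, the first also without untreated IPAH replicate 1 (median -0.25), and the second in the upper 40% of genes and, with the ribosomal one, without untreated IPAH replicate 2 (medians 0.06 and -0.09). Both kept their calls, with larger medians, without untreated IPAH replicate 1 (-0.67 and -0.34) and under median centring (-0.50 and -0.44).

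Between untreated cells ID1 had a log2 difference of 0.79 ± 0.31 (adjusted p = 0.356), ID3 one of -1.49 ± 0.34 (adjusted p = 0.138), SMAD6 one of -0.88 ± 0.78 and KCNA5 one of 0.92 ± 0.43, and none passed. With the isolate as a random block 78 genes passed (37 higher, 41 lower), and without the variance trend 19 did. The count was 16 without either normotensive BMP-2 array, and 31 and 26 without untreated IPAH replicate 1 and 2. Of the named genes CXCL6 lost its call under 5 of 16 alternatives (adjusted p up to 0.114) and PTGS2 under 3 (up to 0.0710), among them the offset of 1 and the loss of either normotensive BMP-2 array, and CXCL6 also without untreated IPAH replicate 1. BST2 lost its call under 7 of 15, TBX2 under 7 of 16, MEST and OSR2 under 6 of 14, THBS2 under 5 of 16, SECTM1 under 4 of 15 and RCAN2 under 1 of 15. CSF3, IL1B, TNFAIP3, STC1, LRRC15, IER3, NAMPT, SELENOP, ADH1A, ADH1B, PTN and NOTCH3 kept theirs under every alternative run. Each alternative read the probe set chosen for the gene, so the second one of ADH1A had no part in this. With an offset equal to the median signal NOTCH3 was at 2.69, MEST at 2.41, OSR2 at 2.35, RCAN2 at 2.37 and SECTM1 at 2.30, all past the threshold. Unadjusted, 617 genes had a p under 0.05.

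**Figure D3:**
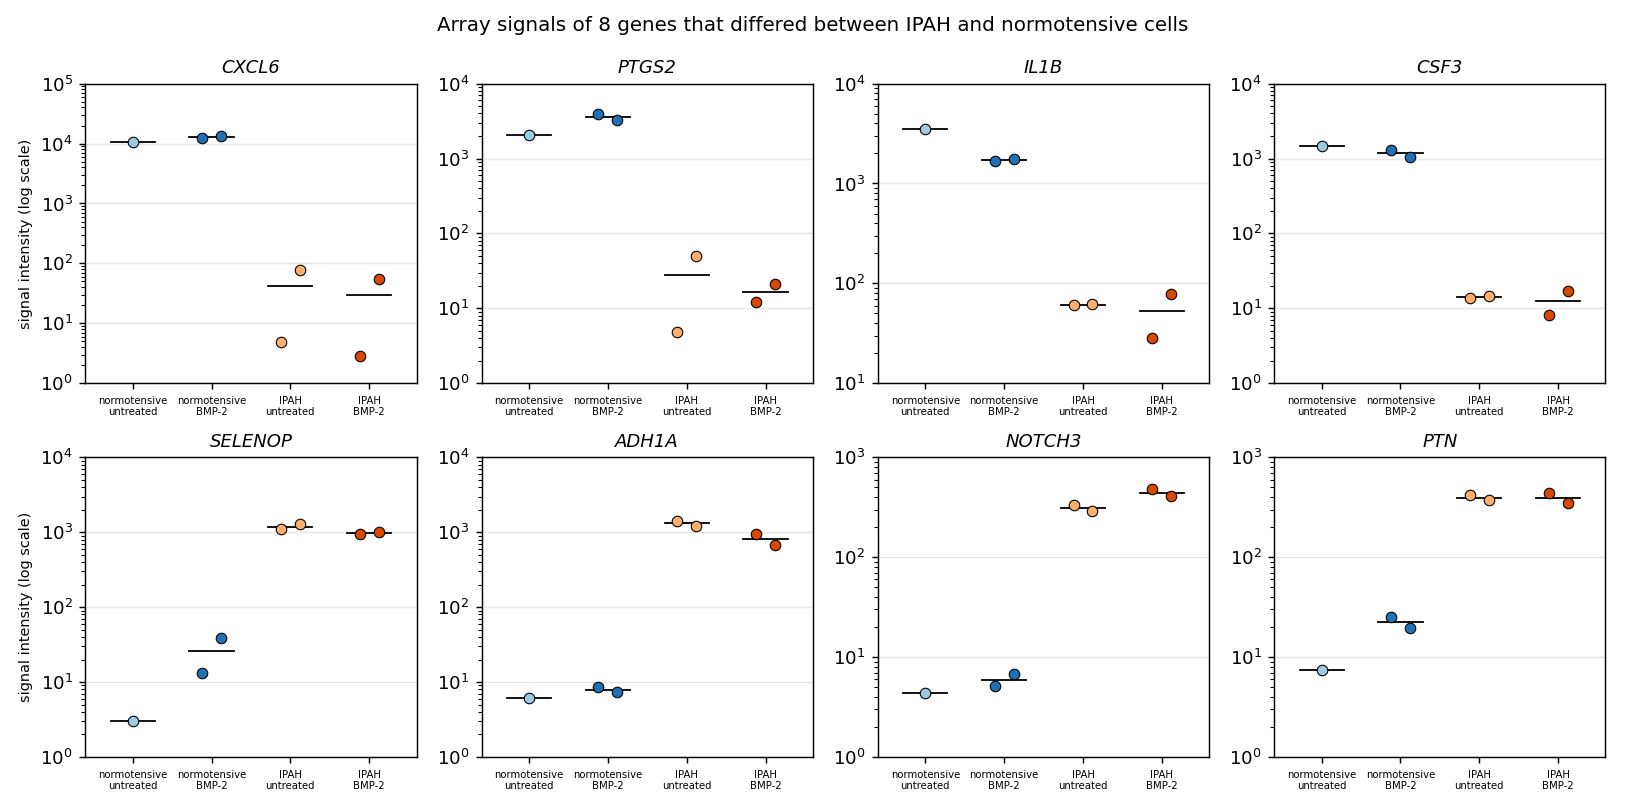
Signal intensity on a log axis for 8 genes that differed between origins, with a point for each of the 7 arrays and a line at each group mean. CXCL6, PTGS2, IL1B and CSF3 were lower on every IPAH array than on every normotensive array, and SELENOP, ADH1A, NOTCH3 and PTN were higher.

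With BMP-2, IPAH and normotensive cells (2 arrays each) differed in 91 genes, 32 higher and 59 lower in IPAH. CXCL6 had a log2 difference of -8.61 ± 0.88 (adjusted p = 0.00586), with a signal of 12846 ± 857 (SD, n = 2) in normotensive and 29.3 ± 37.5 (n = 2) in IPAH cells. PTGS2 was at -6.92 ± 0.56 (adjusted p = 0.00289), and the chemokine genes CXCL1 at -7.34 ± 1.05 (adjusted p = 0.0205), CXCL8 at -5.96 ± 0.87 (adjusted p = 0.0215) and CXCL2 at -5.60 ± 0.83 (adjusted p = 0.0222). CSF3 (-5.55 ± 0.31), IL1B (-4.82 ± 0.38), STC1 (-4.39 ± 0.35), TNFAIP3 (-4.26 ± 0.25) and NAMPT (-3.90 ± 0.26) completed the 10 lowest.

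The 10 highest held ADH1A (5.29 ± 0.29, adjusted p = 0.00106), SELENOP (4.74 ± 0.36), IGFBP2, a binding protein of insulin-like growth factors (4.70 ± 0.77), NOTCH3 (4.59 ± 0.31, adjusted p = 0.00184) and the lipid carrier APOE (4.59 ± 0.78, adjusted p = 0.0385). They also held HSPB6, a small heat shock protein of smooth muscle (4.51 ± 0.52), the transglutaminase TGM2 (4.09 ± 0.60), LRRC32, which anchors latent TGF-beta (3.97 ± 0.70), TBX2 (3.78 ± 0.52) and the glutathione peroxidase GPX3 (3.77 ± 0.31). The second probe set of ADH1A went the other way, at -0.62.

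In the inflammatory list 11 of 30 members were lower with BMP-2 and none higher, and 20 were lower and 1 higher adjusted over the list alone. Its median was -1.97 (camera adjusted p = 4.0e-22, adjusted p = 0.150 with an estimated correlation), or -1.31 with an offset equal to the median signal and -3.13 in the upper 40% of genes. Of 32 hypoxia and glycolysis genes 7 were lower, among them ENO2 (-2.34 ± 0.27), LDHA (-1.73 ± 0.22), PFKP (-2.22 ± 0.28) and ENO1 (-1.45 ± 0.21), and 14 were lower adjusted over the list alone. Their median was -0.72 (camera adjusted p = 9.2e-12, adjusted p = 0.108 with an estimated correlation). Of 41 collagen and matrix genes THBS2 (-2.67 ± 0.25), COL16A1 (-3.42 ± 0.54), the perlecan gene HSPG2 (-1.21 ± 0.21) and the fibrillin gene FBN1 (-2.17 ± 0.39) were lower, and 6 were lower adjusted over the list alone. Their median was -0.35 (camera adjusted p = 0.00289, adjusted p = 0.593 with an estimated correlation). Of 21 immediate early genes IER3 (-2.46 ± 0.21) and MAFF (-1.93 ± 0.26) were lower, and 3 were lower adjusted over the list alone, with a median of -0.46 (camera adjusted p = 0.0157, adjusted p = 0.802 with an estimated correlation). None of 19 cholesterol and fatty acid synthesis genes passed by either count. Their median was -0.68 (camera adjusted p = 4.1e-05, adjusted p = 0.593 with an estimated correlation), with LSS at -0.92 ± 0.26 and INSIG1 at -1.58 ± 0.49. Without IPAH BMP-2 replicate 1 and 2 that median was -0.32 and -1.11, and INSIG1 stood at -0.87 and -2.29. The matrix call ended without IPAH BMP-2 replicate 1 (median -0.21), and without replicate 2 the median was -0.56. The immediate early call ended in the upper 40% of genes, without normotensive BMP-2 replicate 1 (-0.61) and without IPAH BMP-2 replicate 2 (0.22), and its median was -0.15 with all probe sets.

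The differences without and with BMP-2, measured on separate arrays of partly the same isolates, overlapped in 15 higher genes, where independent lists of those sizes would share 0.149, and in 23 lower genes, where they would share 0.311. All 32 and 59 genes called with BMP-2 had the same sign without it. Across all genes the log2 differences correlated at r = 0.673. Since the isolates recur in both comparisons, part of this overlap can come from differences between isolates that origin does not set. Both comparisons also share 1 estimate of each gene's spread, so a gene with a small spread can pass in both. The numbers due for independent lists are therefore too low a yardstick.

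The count with BMP-2 was 57 without the variance trend, 8 and 6 without normotensive BMP-2 replicate 1 and 2, and 29 and 58 without IPAH BMP-2 replicate 1 and 2. All 8 and all 6 were among the 91. Of the named chemokine genes CXCL2 lost its call under 5 of 19 alternatives (adjusted p up to 0.231), CXCL8 under 4 (up to 0.232), CXCL1 under 3 (up to 0.212) and CXCL6 under 2 (up to 0.0848). All 4 lost it without either normotensive BMP-2 array, and CXCL1, CXCL2 and CXCL8 also without IPAH BMP-2 replicate 1. PTGS2, IL1B, STC1, THBS2, IER3, ENO2, PFKP, HSPB6 and GPX3 lost theirs under 2 alternatives and NAMPT under 1. LRRC32 lost its call under 9, FBN1 and HSPG2 under 8, APOE and IGFBP2 under 7, COL16A1, LDHA and ENO1 under 5, and TGM2, TBX2 and MAFF under 4. CSF3, TNFAIP3, ADH1A, SELENOP and NOTCH3 kept theirs, by the probe set chosen for each, under every alternative run, and 620 genes had an unadjusted p under 0.05.

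**Figure D4:**
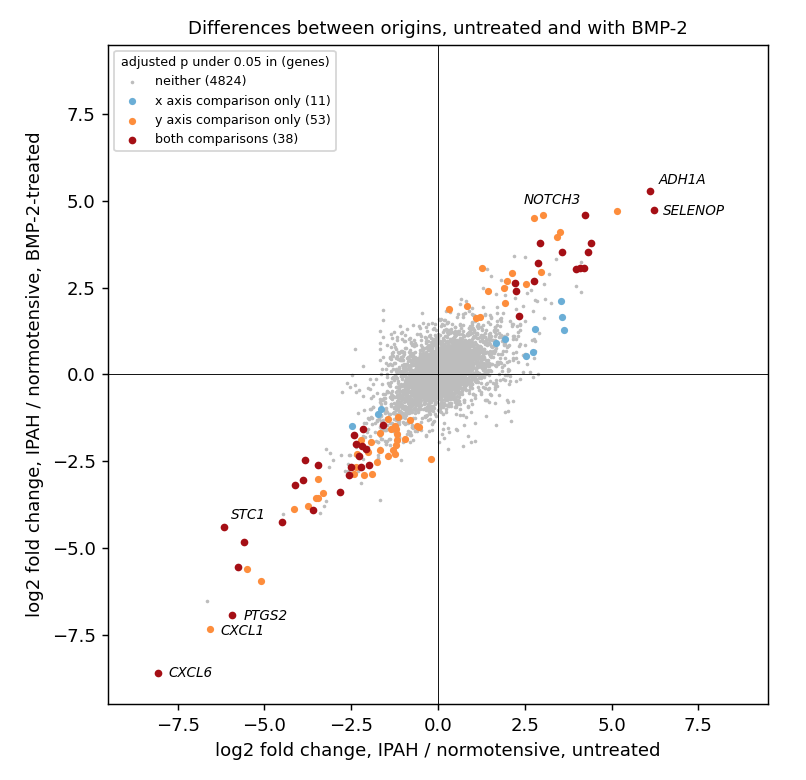
Log2 difference between IPAH and normotensive cells with BMP-2 (vertical) against that without (horizontal) for 4926 genes, coloured by the comparisons in which the gene passed the threshold. The 38 genes past it in both lie along the diagonal, from CXCL6 at -8.06 and -8.61 to ADH1A at 6.11 and 5.29.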

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

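Of the tests below, those on the scaling and on the single untreated array were chosen after the result was seen.

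The difference between the BMP-2 effects of the 2 origins put ribosomal protein genes here, with list medians of 0.23 in IPAH and -0.15 in normotensive cells and a median difference of 0.38 (44 genes, none past the threshold over all genes or adjusted over the list alone, camera adjusted p = 1.4e-08, adjusted p = 0.993 with an estimated correlation). The median change between paired arrays was 0.22 in both IPAH isolates and -0.21 in the 1 paired normotensive isolate, and neither origin's own effect kept its call under quantile normalization, while the log2 3'/5' ratios of GAPDH (-0.34, -0.82 and 0.11) and ACTB (-0.70, -0.94 and 0.26) moved the other way in these pairs. A trend with signal strength is argued against as the whole cause, since 199 other genes of like signal had a median of 0.0871. The ribosomal median exceeded 99.99% of 10000 random lists matched on signal (95% of their medians between -0.01 and 0.25). Ribosomal genes move together (estimated correlation 0.591) and randomly drawn genes do not, so that share overstates how unusual the list was. The bootstrap intervals below also take these genes as independent and are too narrow. The scaling may account for part of it, since quantile normalization left a median of 0.20 (bootstrap 95% interval 0.15 to 0.27) and took the IPAH effect from 0.23 to 0.08. With an IPAH effect of 0.23 (0.17 to 0.28) on one scaling and 0.08 on another, it stays open whether the single untreated normotensive array carries the difference, and RNA quality, which was not tested for this list, and a difference between the cells of the 2 origins stay open as well.

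Probe sets without a single gene symbol lay outside the comparisons, and some passed the threshold when all probe sets were tested: 1 over both origins, 6 between untreated origins and 9 between treated origins. The one over both origins has several symbols and rose with BMP-2 (3.34 ± 0.36, adjusted p = 0.0131). The largest change between untreated origins was that of a probe set with no symbol, lower in IPAH (-4.77 ± 0.51, adjusted p = 0.0125), and the largest between treated origins that of another with no symbol, also lower in IPAH (-2.77 ± 0.45, adjusted p = 0.0322).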

How the results depend on the processing

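The additive origin term with a random isolate block was chosen after the data were seen, and the cause of the changes below was not tested unless said. Of the values of called genes under the alternatives 1073 kept direction and threshold and 244 kept only the direction, and of those of called lists, by camera's direction, 270 and 50 did and 1 reversed, the ribosomal one given below. Of values of genes not called 1740 stayed so with the same sign, 45 passed and 18 changed sign.

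Without the variance trend 1 gene passed for BMP-2 in IPAH cells, 19 between untreated origins and 57 between treated origins, and with the 4 arrays of the comparison alone 1 passed for BMP-2 in IPAH cells. At an adjusted p under 0.10, 91 and 158 genes differed between untreated and treated origins. With the replicate block as a random effect the counts were 5 (IPAH, BMP-2), 3 (normotensive, BMP-2) and 78 (untreated origins), and 238 between origins with the additive term. With the replicate block as a fixed term they were 112 (IPAH), 24 (normotensive), 9 (both origins) and 13 (interaction), the 24 and the 13 resting on 1 normotensive pair, and the pairing gave 19 list calls in those 4 comparisons against 10 without it. Blocking moved no other count by over 1.5 times. List calls numbered 13 under quantile normalization, 31 with all probe sets and 0 with an estimated correlation. The correlation of BMP-2 effects was 0.0897 without a filter and 0.262 in the upper 40% of genes. The ribosomal median between untreated origins was 0.0280 under quantile normalization. The difference of BMP-2 effects was -0.0709 for ID1 and 0.0185 for SMAD7 with an offset of 1, and 0.13 for SMAD7 under quantile normalization, none past the threshold.

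Leaving out 1 array at a time gave 1 to 2 genes for BMP-2 in IPAH cells, 0 to 1 in normotensive cells, 2 to 5 over both origins, 16 to 41 between untreated origins and 6 to 95 between treated origins. It gave 0 for the interaction, 9 to 32 list calls (9 in the 3 comparisons left without the normotensive untreated array, 32 without IPAH BMP-2 replicate 2) and correlations of 0.0563 to 0.189. Where that left a group with 1 array, the array was assumed to vary like the others. The 5 over both origins, without untreated IPAH replicate 1, were ID1, ID3, ACTC1, SMAD6 and SMAD7. Genes short of the threshold changed sign. BCL2 ranged from -0.43 to 1.56 (BMP-2 in IPAH), -0.0415 to 0.96 (both origins), -0.65 to 1.34 (untreated origins), -0.0569 to 1.18 (treated origins) and -0.78 to 1.21 (interaction). SMAD6 ranged from -1.89 to 0.13 (untreated origins), -0.57 to 0.19 (treated origins) and -0.32 to 1.70 (interaction), SMAD7 from -0.84 to 0.61 and ID1 from -0.24 to 0.26 (both interaction).

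Not run were a random isolate block for the lists, which camera does not take, and a fixed isolate term between origins, in which the isolates are nested. Signal limits what was tested, since genes whose probe set lay under a signal of 42.3, among them BMPR2 and ID2, had no test.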

Other observations

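The tests of the inflammatory genes below were chosen after the result was seen, and those of the splits and of the exchanged labels before.

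Beyond the lists described so far, growth factor genes with BMP-2 held members of both signs in IPAH against normotensive cells. Of 39 tested, 3 were higher and 3 lower, and 3 and 5 adjusted over the list alone. PTN (3.52 ± 0.30), the mural cell receptor PDGFRB (2.62 ± 0.29) and IGFBP2 (4.70 ± 0.77) were higher, and FGF2 (-2.17 ± 0.29) and the angiopoietin receptor TEK (-3.55 ± 0.52) were among those lower. The list's median was -0.08 (camera adjusted p = 0.245). Among matrix proteases and their inhibitors PLAU was higher (1.68 ± 0.28) and its receptor PLAUR (-1.56 ± 0.23) and the gelatinase MMP2 (-1.69 ± 0.25) were lower, 1 and 2 of 20 by either count. The thrombin receptor F2R was higher (2.92 ± 0.39) and PTGS2 lower among 23 vasoactive genes (3 and 1 adjusted over the list alone). CAV1, the caveolin gene, was the 1 contractile gene of 23 to differ (2.70 ± 0.26, 1 adjusted over the list alone), and NOTCH3 the 1 of 9 NOTCH pathway genes (1 adjusted over the list alone). SFRP1, a WNT antagonist, was higher (2.39 ± 0.23) among 18 WNT genes (2 higher and 1 lower adjusted over the list alone) and 17 fibroblast markers (1 and 1). GAS1 was lower (-1.56 ± 0.22) among 18 growth arrest genes (1 higher and 2 lower adjusted over the list alone), and BST2 (-3.05 ± 0.49) among 28 interferon genes (2 and 3). PLAU lost its call under 10 of 19 alternatives, PLAUR, MMP2 and GAS1 under 5, BST2 under 5 of 18, FGF2 under 4 of 19, TEK under 4 of 18, F2R and PDGFRB under 3 of 19, and PTN, CAV1 and SFRP1 under 2 of 19. BST2 was at -2.03 with an offset equal to the median signal.

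None of these lists had a call with BMP-2, nor did the following, none of whose members passed over all genes except TEK, which is also an endothelial marker, and PLAU and PLAUR, which also belong to the TGF-beta response. The median difference was -0.34 for BMP-SMAD targets, 0.15 for BMP and TGF-beta ligands, receptors and SMADs, -0.04 for the TGF-beta response, 0.41 for cell cycle genes, -0.07 for apoptosis, 0.02 for 13 potassium channels, 0.31 for calcium handling and 0.10 for sodium, chloride and transporter genes. It was -0.24 for the unfolded protein and heat shock response, 0.11 for oxidative phosphorylation, 0.14 for ribosomal proteins, 0.58 for 10 osteogenic genes, -0.15 for 7 endothelial markers, 0.57 for 7 leukocyte markers and -0.08 for 5 epithelial markers. Adjusted over the list alone, 4 ligands or receptors were higher and 3 lower, 1 and 2 TGF-beta response genes, 2 and 1 calcium genes and 1 and 1 endothelial markers. By that count 3 apoptosis genes and 1 gene each of the BMP-SMAD, stress and osteogenic lists were lower, and no gene of the other lists differed. Camera's direction was opposite to the median for the potassium channel, epithelial and interferon lists. Leukocyte and endothelial markers are given beside the inflammatory genes because such cells carry some of the same transcripts.

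Inflammatory genes were lower in IPAH cells on every array pair for CXCL6, PTGS2, IL1B and CSF3. Leukocyte markers, without the filter, had a median difference of 0.0775 (bootstrap 95% interval -0.18 to 0.69). That median cannot decide whether leukocytes were in the normotensive cultures, since most markers were dim. Only 7 of the 27 passed the signal filter, and the median of the mean normotensive signals was 17.97. Of those 7, 5 were higher in IPAH with BMP-2. The abundant leukocyte genes LYZ, TYROBP and CORO1A had mean normotensive signals of 13.6, 7.90 and 4.27, which gives no sign of such cells. However, CXCR4 (-1.76), CD14 (-1.16) and CD68 (-0.63) were lower in IPAH. CD68 was the brightest marker, with mean signals of 480 in normotensive and 363 in IPAH cells. Leukocytes therefore stay open. Scaling is argued against, since the list's median was -2.04 (bootstrap interval over genes -3.53 to -1.34) under quantile normalization. The 3'/5' ratios were compared over 12 pairs of a normotensive and an IPAH array. GAPDH was higher in the normotensive array in 4 pairs and ACTB in 8, so neither separated the origins over all arrays. Those pairs mix the treatments. Without BMP-2 the log2 ratio of GAPDH was 0.65 in normotensive and 1.02 and 1.71 in IPAH cells. That of ACTB was 3.44 against 3.47 and 4.49. With BMP-2 ACTB stood at 3.70 and 4.80 against 2.78 and 3.55, while GAPDH overlapped. RNA quality therefore stays open, although ACTB parted the origins in opposite directions while the list was lower in IPAH both times. The log2 ratios themselves ran from 0.65 to 1.71 for GAPDH and from 2.78 to 4.80 for ACTB, so every array had more signal at the 3' end. A batch of culture or preparation cannot be told apart from origin, because the 2 isolates of each origin were not shared between origins. A candidate explanation is thus either the disease or any other difference between these few isolates or their RNA. Passage, stimulation or leukocytes in the cultures would be examples, and the data hold no test between these explanations.

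The count of 4 genes that rose with BMP-2 over both origins was set against other splits of the 7 arrays into 4 and 3. Of 35 splits 34 could be fitted, since 1 coincides with origin. Only the real one (1 split) gave a count as large, and the highest other count was 1. These splits treat all arrays as exchangeable, while the isolates pair them. Of the 8 splits that, like the real one, part all 3 pairs, the others gave 0 genes, and 8 splits are too few for a share under 0.05.

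More genes responded to BMP-2 in IPAH cells when the isolate was a fixed block, 112 (70 higher, 42 lower) against 2. Among them, named after their values were seen, were IGFBP3 (2.07 ± 0.21), ACTA2 (1.48 ± 0.18), the matrix gene POSTN (1.15 ± 0.16), CCN2 (1.04 ± 0.17) and LDHA (0.93 ± 0.17), all higher, and ADM, which encodes the vasodilator adrenomedullin (-1.33 ± 0.23). These standard errors come from a common trend, not from each gene's own spread. The signal of ACTA2 rose from 603.8 to 3658.8 in IPAH isolate 1 and from 2441.4 to 3206.1 in isolate 2. Its standard error does not show that difference. An error estimate that is too small could produce a count of 112, and with the labels of 1 IPAH isolate exchanged the blocked fit gave 0 genes. That test decides little, because the fit's 1 residual degree of freedom is the very contrast that the exchange tests, so its outcome was largely set by the design, and the median standard error rose from 0.354 to 0.407. Whether the blocked count overstates the response therefore stays open.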
